A study of Mus musculus with 4 samples.

How the data were processed

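Total RNA of mouse primary cells was sequenced in 4 libraries. The labels give the assay as total RNA-seq and the molecule as total RNA, while the library protocol they cite is titled for poly(A)-selected RNA, and a protocol for differentiating CD4 T cells is cited as well. All 4 samples have the label regulatory T cell and form 1 group, with replicate numbers from the labels. The labels give 4 biosamples and 1 donor record and no sex. The column name inside each file carries the text mmTreg, the text activated before a mark of 0 h, and a replicate number. That number matches the label in all 4 files.

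The deposited values are raw fragment counts per gene. Per the file headers, counts were made with featureCounts 1.4.6-p4 over exons of GENCODE M13 genes on the mouse build mm10, from paired-end reads with both ends aligned and the strand setting 2, which is reverse-stranded. Per the file headers, the aligned reads were named for STAR, and no option to count fragments with several alignments or fragments over several genes was set, so these were left out. Reads of near-identical genes are therefore missing from the counts rather than divided among copies. The exon length per gene was taken from the same deposited count files. No step was applied to the reads here.

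The design fixed before the data were examined had assumed expected counts and TPM from the program RSEM. The files hold raw counts instead, so the counts were used as they stand, and TPM was computed here from each count and the exon length in the file. The alternatives that needed posterior mean TPM could not be run. Gene symbols, biotypes and coordinates came from GENCODE M21 on the same build, matched on gene identifiers without version, for 50376 of 50600 genes (99.6%). Coordinates are 1-based.

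Gene lists and tests were fixed before the data were examined. The 42 lists cover lineage factors, regulatory T cell genes, suppressor molecules, effector regulatory T cells, responses to growth factors and cytokines, T helper lineages, naive and activated T cells, other cell types, metabolism, stress, interferon, RNA classes, housekeeping and sex. Each has its result in the report. Of 517 distinct list symbols, 512 matched a gene, and those not matched were Folr4, whose current name Izumo1r is in the same list, Il26, Trgc1, Trgc2 and Ero1a. Named genes are all lineage factors, all members of the regulatory T cell and sex lists, the 3 highest and 2 lowest members of each list by mean TPM, the 15 genes with the highest mean TPM and the 5 most used V segments per chain. They also include the 20 genes called variable between libraries with the largest range among those with a mean of at least 5 CPM. Any other gene was named after its values were seen. Some genes that these rules include are not reported here by name, though they stayed in the list results.

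Ratios of Foxp3 to other factors used TPM plus 0.1. Differences between list medians used log2(TPM+0.1) within a library, with shared members left out of both lists. Both were tested over libraries with an exact two-sided sign-flip test, whose smallest p with 4 libraries is 2 of 16 sign patterns (0.125), and adjusted by the Benjamini-Hochberg method. List levels were set against 10000 random lists of protein-coding genes with a count in some library. Spread of lists used TMM-scaled log2(CPM+1) and 10000 random lists matched in 20 bins of mean expression. Genes variable between libraries were tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM, an intercept-only glmQLFit and the residual deviance at the trended dispersion against chi-square on 3 degrees of freedom, at an adjusted p of 0.05. This filter required counts in all 4 libraries, so Y-linked genes were not tested by it. DESeq2 1.42.0 and limma 3.58.1 gave alternatives. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

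The edgeR step was tested on 12554 genes simulated from the real means, of which 200 were changed, with 2 false calls (1.46% of calls). Each gene was simulated at the trended dispersion that the test uses. The result therefore does not measure false calls among real genes, whose dispersion can lie off the trend. The list step was tested on 21256 genes with 3 lists raised 1.5-fold in 1 library, all of which passed the 95th percentile, as did 4 of the 39 lists left unmoved. Sequence sharing was measured as the share of 50-base words, sampled every 10 bases of a gene's M21 transcripts, that occur in transcripts of another gene on either strand, for 538 genes. It exceeded 50% in 52 of them. Read length is not given in the sources used here. Depth ran from 23000465 to 62090744 counts per library. A gene was called detected at 1 TPM in all libraries, and a floor of 3 counts was used where a gene had none. Such floors cover counting error only. Alternatives changed pseudocounts, thresholds, normalization, filters, tools and the unit, and left out each library in turn. No sample, column or gene row was left out.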

Results

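RNA was measured in 4 libraries of mouse primary cells that carry 1 label, regulatory T cell, from the C57BL/6NJ strain. Regulatory T cells are CD4 T cells that hold back immune responses and are defined by the transcription factor Foxp3. The libraries were biological replicates 1 to 4, each from its own biosample, and the labels name a single donor record for all 4. No second group was analysed here, so genes and gene lists were compared within each library, and the spread between libraries was described. The p-values below measure only the spread between these 4 samples, which may in part be technical. Total gene counts were 25573253 in replicate 1, 62090744 in replicate 2, 23000465 in replicate 3 and 61943411 in replicate 4, a 2.70-fold range. Unless stated otherwise, levels are length-normalised abundances (TPM) as mean ± SD with n = 4.

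A total of 11670 genes reached 1 TPM in all 4 libraries, of which 9948 (85.2%) were protein-coding. Protein-coding genes took 98.3% ± 0.0678 of the counts (SD, n = 4). The 10 most abundant genes took 9.62% ± 0.359 of TPM and 5.13% ± 0.0961 of counts (SD, n = 4). The translation factor Eef1a1 (15474 ± 963 TPM) lay highest, followed by mt-Co1 (14526 ± 1133 TPM) and Rplp1 (12750.5 ± 1316 TPM), a mitochondrial oxidase subunit and a ribosomal protein. The next places held Gm23935 (9705 ± 1080.1 TPM), Rpl8 (9248 ± 655 TPM), Actb (8006 ± 325 TPM), Rps15 (7286 ± 579 TPM) and Eef2 (6456 ± 306 TPM). Below them came mt-Cytb (6396 ± 659 TPM), Rplp0 (6289.5 ± 529 TPM), H2-K1 (5298 ± 589 TPM), B2m (5115 ± 448 TPM), Rpl4 (4571 ± 178 TPM) and Tmsb4x (4416 ± 256 TPM). Gm23935 is a microRNA gene of 57 exon bases on chromosome 16, 11144125 to 11144181. Its TPM rank of 4 fell to 1451 when genes were ranked by counts, and its single sampled 50-base word also occurs in transcripts of other genes, so its level is uncertain. Between libraries, Pearson correlations of log2(TPM+1) across genes ran from 0.992 to 0.995 over the 6 pairs, and Spearman correlations from 0.917 to 0.927. Genes are not independent replicates, so no p-value is attached to these. As a check for duplicated libraries, the chi-square statistic of the counts per degree of freedom was at least 7.13 in every pair, so none is a resampling of another. The biological coefficient of variation was 0.0849.

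The lineage factors were compared first, since the label names a lineage. Foxp3 lay at 8.28 ± 0.867 TPM, on 234 to 572 counts per library. Gata3, the factor of T helper 2 cells, stood above it at 53.6 ± 3.401 TPM, as did Bcl6, the factor of follicular helper T cells, at 15.2 ± 0.933 TPM. Tbx21, the factor of T helper 1 cells, stood below Foxp3 at 0.817 ± 0.323 TPM. The log2 ratio of Foxp3 to Gata3 was -2.68 ± 0.18 and that to Bcl6 was -0.87 ± 0.09 (SD, n = 4), so Gata3 exceeded Foxp3 6.42-fold. The ratio to Tbx21 was 3.25 ± 0.49, in favour of Foxp3. With 1 TPM added in place of 0.1 the ratio to Tbx21 was 2.36, and without the length correction it was 3.86 and that to Bcl6 -1.62, so these sizes depend on the scale. Each of these 3 ratios had its sign in 4 of 4 libraries. The exact two-sided sign-flip p was 0.125 for each, raw and adjusted over the 4 ratios of the design by the Benjamini-Hochberg method. That is the smallest p that 4 libraries allow, so this design cannot reach 0.05. On the mouse genome build mm10 (GRCm38), Foxp3 (ENSMUSG00000039521.12) lies on chromosome X, 7579676 to 7595243, Gata3 (ENSMUSG00000015619.10) on chromosome 2, 9857078 to 9890034, Bcl6 (ENSMUSG00000022508.5) on chromosome 16, 23965052 to 23988852 and Tbx21 (ENSMUSG00000001444.2) on chromosome 11, 97098071 to 97115331. In GENCODE M21, 18.6% of the exon bases of Foxp3 lie inside exons of another gene on the same strand. Fragments over such bases may have been left out of the counts, which were made on GENCODE M13. That loss was not measured.

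Genes enriched in regulatory T cells were present at uneven levels. Of the 19 measured members of the regulatory T cell list, 13 reached 1 TPM in all 4 libraries. The list's median was 5.17 ± 2.18 TPM, at percentile 13.0 of 10000 random lists of as many protein-coding genes and at 0 among random lists of expressed genes. The highest members were the folate receptor family gene Izumo1r (167 ± 8.51 TPM), the receptor Tnfrsf18 (107 ± 3.805 TPM), known as GITR, the actin-capping gene Capg (50.05 ± 2.72 TPM) and Tnfrsf4 (33.5 ± 6.35 TPM), known as OX40. A middle group held Gpr83 (13.2 ± 2.503 TPM), Nt5e (13.1 ± 1.87 TPM), Ikzf4 (9.22 ± 1.18 TPM), Foxp3 (8.28 ± 0.867 TPM), Ctla4 (7.77 ± 0.959 TPM), Il2ra (5.52 ± 2.76 TPM) and Cd83 (2.46 ± 0.796 TPM). Ctla4 is an inhibitory receptor and Il2ra the alpha chain of the interleukin-2 receptor. The genes Tigit (1.44 ± 0.391 TPM), Ikzf2 (1.34 ± 0.194 TPM) and Nrp1 (1.29 ± 0.173 TPM) lay close to 1 TPM. The remaining 5 members, Lrrc32 (0.355 ± 0.131 TPM), Itgae (0.248 ± 0.133 TPM), Klrg1 (0.227 ± 0.109 TPM), Entpd1 (0.1602 ± 0.0354 TPM) and Socs2 (0.135 ± 0.0552 TPM), lay below 1 TPM in every library. Without replicate 3 the list's median was 4.32 TPM. Il2ra was the middle member in replicates 1, 2 and 4, so the list's median there is the level of that gene, which varied between libraries.

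Genes of naive and central memory T cells were among the most abundant messages. All 15 members of this list exceeded 5 TPM in every library, and the list's median was 569.7 ± 25.6 TPM, above all 10000 random lists. The transcription factor Tcf7 (2932 ± 117 TPM), the lymph node homing receptor Ccr7 (1083 ± 37.7 TPM) and the factor Ets1 (933 ± 83.7 TPM) led, and even the lowest members, Klf3 (87.6 ± 6.71 TPM) and Foxp1 (86.5 ± 4.19 TPM), exceeded every regulatory T cell gene except Izumo1r and Tnfrsf18. The T cell receptor complex and its signalling genes had a median of 722 ± 2.42 TPM, with all 18 members detected. The receptor constant genes Trac (3435 ± 137 TPM), Trbc2 (2840.1 ± 55.7 TPM) and Trbc1 (1916 ± 89.97 TPM) were highest in that list, and Bcl11b (239.6 ± 17.4 TPM) and Cd28 (175 ± 19.9 TPM) lowest. Trbc1 and Trbc2 share over 40% of their sampled 50-base words with other genes (41.4% and 44.6%), so the division between them is uncertain.

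**Figure D1:**
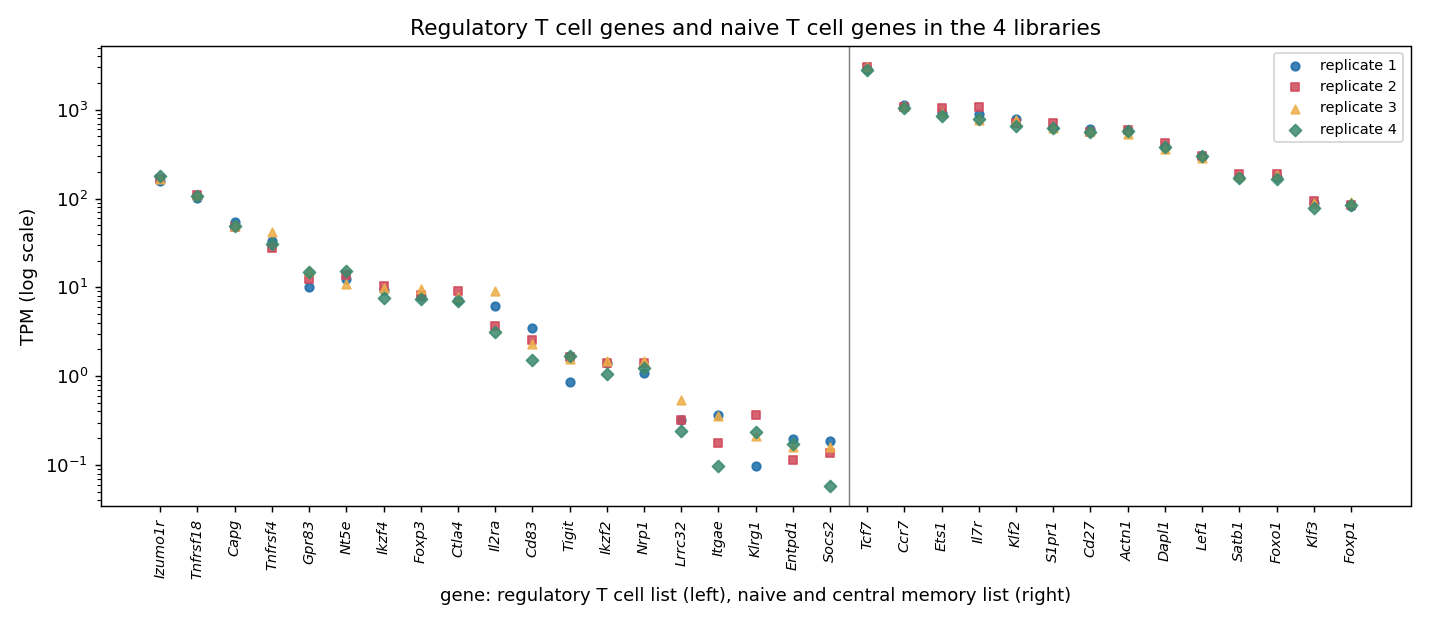
TPM on a log axis of each measured gene of the regulatory T cell list and of 14 genes of the naive and central memory list, with 1 point for each of the 4 libraries. Foxp3 lies between 7.39 and 9.46 TPM, while the naive and central memory genes lie far higher, from Foxp1 at a mean of 86.5 TPM to Tcf7 at 2932 TPM.

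Within each library, the median log2(TPM+0.1) of the regulatory T cell list was set against that of lists for other lineages. It lay below the naive and central memory list, with a mean difference of -6.85 ± 0.65 (SD, n = 4), so that list was 116-fold higher. It also lay below the follicular helper list, by a mean difference of -1.44 ± 0.59. Without Foxp3, Il2ra and Ctla4 these differences were -8.13 and -2.72. It lay above the T helper 1 (1.58 ± 0.58) and T helper 17 lists (3.41 ± 0.76). The T helper 2, conventional T cell cytokine, granulocyte and mast cell, stromal, red cell and platelet, and dendritic lists had medians near or below the 0.1 TPM that was added. For these lists the size of the difference is set largely by that addition, and only the sign is read. It was 5.29, 5.25, 5.62, 5.48, 5.03 and 4.55 in that order, and 2.51, 2.51, 2.56, 2.54, 2.47 and 2.40 with 1 TPM added. Among the other lists it was 2.89 ± 0.61 against gamma-delta and innate-like T cells, 2.62 ± 0.54 against natural killer and innate lymphoid cells, 2.46 ± 0.71 against macrophages and 0.66 ± 0.56 against B cells. All of these signs held in 4 of 4 libraries, with an exact two-sided sign-flip p of 0.125, the smallest possible, and 0.133 after adjustment over the 16 lists. Against the CD8 and cytotoxic list the difference of 0.06 ± 0.53 was smaller than the spread between libraries, with its sign in 2 of 4 libraries and an exact p of 0.875. It turned negative without replicate 1 (-0.06) and without replicate 3 (-0.12). Against the thymocyte list the sign depends on the measure. The difference of log medians was 1.11 ± 0.58, positive in 4 of 4 libraries (exact p 0.125), while the median TPM of thymocyte genes was the higher in every library, because the 2 middle members of that list lie far apart. The signs against CD8, B cell and thymocyte lists turned when Foxp3, Il2ra and Ctla4 were left out, to -1.22, -0.62 and -0.17. The same change left 0.30 ± 0.24 against T helper 1, which was 0.78 with the mean over members. With 1 TPM added, the difference from thymocytes was 0.10 ± 0.47 with an exact p of 0.75, so its sign no longer held in every library, and those from T helper 1 and T helper 17 were 1.17 and 2.09.

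**Figure D2:**
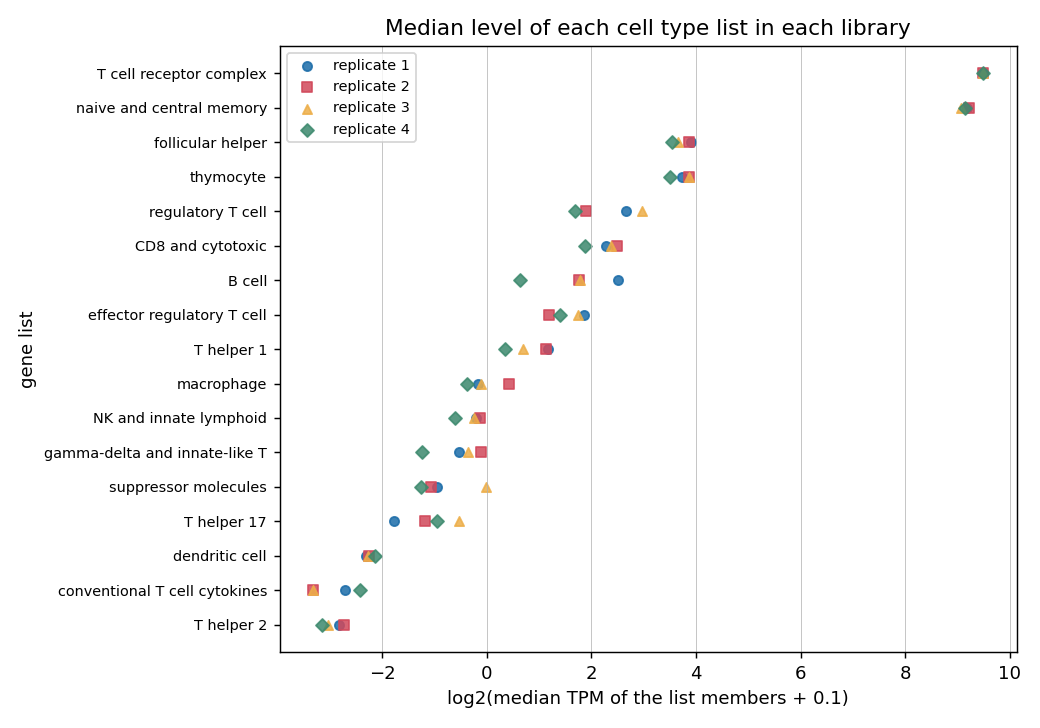
The log2 of the median TPM plus 0.1 of each cell type list (rows), with 1 point for each of the 4 libraries. The T cell receptor complex and the naive and central memory lists lie apart from the others, at mean medians of 722 and 569.7 TPM, while the regulatory T cell list lies at 5.17 TPM.

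The lists of T helper lineages were detected in part. The T helper 1 list had 7 of 14 members at 1 TPM in all libraries and a median of 1.73 ± 0.4704 TPM, led by Runx3 (88.8 ± 4.43 TPM), Il18r1 (59.2 ± 7.94 TPM) and Stat4 (54.6 ± 5.15 TPM), with Ifng (0.0855 ± 0.104 TPM) and Hlx (0.0246 ± 0.0346 TPM) at its foot. The T helper 2 list had 4 of 12 detected members and a median of 0.0309 ± 0.01702 TPM. Besides Gata3 its highest members were Epas1 (25.9 ± 1.22 TPM) and Ccr8 (7.18 ± 2.61 TPM), and Areg and Il24 had no count in any library. For Areg, 3 counts would have given up to 0.37 TPM. The T helper 17 list had 3 of 13 detected members and a median of 0.385 ± 0.166 TPM. It was led by Tmem176b (3.42 ± 0.764 TPM), Rora (1.901 ± 0.208 TPM) and Tmem176a (1.62 ± 0.468 TPM), with no count for Il23r and Ccl20. The follicular helper list had 8 of 11 detected members and a median of 13.4 ± 1.55 TPM, from Il6ra (239 ± 10.5 TPM), Btla (136 ± 12.3 TPM) and Pou2af1 (22.4 ± 0.186 TPM) down to Ascl2 (0.127 ± 0.174 TPM) and Il21 (0.0848 ± 0.0635 TPM). Of the 15 conventional T cell cytokines only 2 were detected in all libraries, Lta (62.8 ± 6.29 TPM) and Tnf (41.6 ± 3.49 TPM), both of the tumour necrosis factor family. The third was Il2 (0.442 ± 0.3304 TPM), on 3 to 7 counts per library, and Il22 and Il6 had no count. The list's median was 0.0343 ± 0.0418 TPM, and 0.0175 TPM without replicate 4.

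Genes tied to regulatory T cell function were mixed. Among suppressor molecules, 7 of 18 were detected, with a median of 0.4996 ± 0.258 TPM (percentile 0.45). The list held Lgals1 (200.3 ± 7.29 TPM), Tgfb1 (111 ± 3.51 TPM) and Icos (38.5 ± 4.64 TPM) at its top, while the suppressive cytokine Il10 had 1 count over the 4 libraries and Areg none. For Il10, 3 counts would have given up to 0.343 TPM. Of the list fixed for effector regulatory T cells, 11 of 15 members were detected, at a median of 2.88 ± 0.625 TPM. The factors Batf and Bach2 (103 ± 14.4 and 85.9 ± 5.03 TPM) and Tnfrsf1b (66.5 ± 3.79 TPM) were highest, and Klrg1 (0.227 ± 0.109 TPM) and Il1rl1 (0.0617 ± 0.03405 TPM) were lowest. Bach2 restrains the effector state, so its level is not read as a sign of effector cells. Genes that transforming growth factor beta raises had 11 of 15 detected members and a median of 13.4 ± 1.12 TPM, led by Ski (276 ± 3.703 TPM), Smad7 (145 ± 7.497 TPM) and Id3 (88.3 ± 9.64 TPM), with Ltbp3 (0.0193 ± 0.0132 TPM) lowest. Gut homing genes that retinoic acid raises had 5 of 9 detected members and a median of 1.75 ± 0.363 TPM. The integrin chains Itgb7 (1517 ± 101 TPM) and Itga4 (122 ± 9.69 TPM) and the receptor Rara (96.6 ± 8.32 TPM) were abundant, and Gpr15 (0.131 ± 0.157 TPM) and Cyp26b1 (0.00521 ± 0.0104 TPM) were not. Interleukin-2 and STAT5 genes had 12 of 15 detected members, a median of 53.5 ± 2.36 TPM and percentile 98.2 (88.2 among expressed genes), led by Il2rg (641 ± 34.3 TPM), Stat5b (207 ± 10.4 TPM) and Socs3 (206 ± 18.9 TPM). The lowest were Gzmb (0.485 ± 0.1798 TPM) and Socs2. Inhibitory receptors had 10 of 13 detected members and a median of 7.77 ± 0.959 TPM, from Vsir (331 ± 12.2 TPM) and Cd96 (246 ± 12.5 TPM) and Btla down to Cd244a (0.0992 ± 0.07701 TPM) and Havcr2 (0.07904 ± 0.0528 TPM). Chemokine receptors and integrins had 10 of 18 detected members and a median of 1.61 ± 0.433 TPM, with Itgb7 and Ccr7 highest, Ccr1 (0.0612 ± 0.0449 TPM) near the floor and no count for Ccr10.

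Activation, division and stress genes spanned a wide range. Genes raised by T cell receptor signals had 15 of 16 detected members and a median of 33.8 ± 1.898 TPM. They were led by Cd5 (943 ± 53.7 TPM), Cd40lg (269 ± 6.38 TPM) and Nfatc1 (111 ± 3.099 TPM), and the division marker Mki67 (1.93 ± 0.457 TPM) and the early gene Nr4a2 (1.14 ± 0.447 TPM) were lowest. Genes of dividing cells had 15 of 22 members detected at a median of 2.89 ± 0.215 TPM. The replication genes Pcna (124 ± 5.81 TPM), Mcm6 (68.04 ± 2.72 TPM) and Mcm3 (62.6 ± 1.25 TPM) were highest, and the mitotic genes Ccnb1 (0.534 ± 0.197 TPM) and Bub1 (0.343 ± 0.221 TPM) lowest. Immediate early and heat shock genes had 11 of 14 detected members, a median of 98.001 ± 11.4 TPM and percentile 99.9, led by Hspa8 (910.3 ± 131 TPM), Jund (520.3 ± 29.3 TPM) and Btg2 (359 ± 16.6 TPM), with Fosb (0.671 ± 0.236 TPM) and Hspb1 (0.249 ± 0.298 TPM) lowest. Hspa8 shares 63.6% of its sampled 50-base words with other genes. The p53 and cell death list had 10 of 13 detected members and a median of 39.1 ± 2.403 TPM, led by Bax (153 ± 10.1 TPM), Ccng1 (145 ± 8.69 TPM) and Trp53inp1 (131 ± 9.04 TPM), with Pmaip1 (0.697 ± 0.194 TPM) low and no count for Eda2r. Unfolded protein and amino acid stress genes had 11 of 14 detected members and a median of 26.4 ± 1.49 TPM, from Atf4 (301 ± 13.2 TPM), Hspa5 (219 ± 11.6 TPM) and Herpud1 (128 ± 6.603 TPM) to Atf3 (0.242 ± 0.225 TPM) and Chac1 (0.0543 ± 0.0873 TPM). Genes that low oxygen raises had 14 of 17 detected members and a median of 15.95 ± 0.461 TPM, from Ddit4 (1071 ± 91.6 TPM), Pdk1 (203 ± 19.2 TPM) and Egln1 (93.7 ± 2.27 TPM) to Car9 (0.602 ± 0.174 TPM) and Adm (0.0345 ± 0.0689 TPM).

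Markers of other cells differed in how far they were detected. The B cell list had 7 of 12 detected members and a median of 3.42 ± 1.71 TPM. Its immunoglobulin genes Ighm (1103 ± 67.4 TPM), Igkc (37.3 ± 21.9 TPM) and Ighd (12.5 ± 3.85 TPM) were highest, and Jchain (0.366 ± 0.168 TPM) and Ebf1 (0.154 ± 0.0914 TPM) lowest. Unlike Igkc and Ighd, Ighm was not called variable between libraries (below), so its level is not read as a measure of B cells. The CD8 and cytotoxic list had 7 of 10 detected members and a median of 4.74 ± 0.841 TPM, led by Prf1 (75.3 ± 2.76 TPM), Cd8b1 (39.95 ± 2.55 TPM) and Klrd1 (32.6 ± 5.52 TPM), while Gzmb and Gzmk (0.192 ± 0.145 TPM) were lowest. The natural killer and innate lymphoid list had 4 of 12 and a median of 0.721 ± 0.113 TPM, with Id2 (67.4 ± 4.18 TPM), Gzma (4.75 ± 1.51 TPM) and Fcer1g (2.82 ± 0.0922 TPM) above Klrk1 (0.1598 ± 0.1101 TPM) and Kit (0.104 ± 0.0183 TPM). The gamma-delta and innate-like list had 1 of 8 and a median of 0.603 ± 0.211 TPM, with Trdc (8.37 ± 0.874 TPM), Blk (1.42 ± 0.731 TPM) and Tcrg-C4 (0.989 ± 0.985 TPM) above Zbtb16 (0.0981 ± 0.103 TPM) and Sox13 (0.0492 ± 0.0364 TPM). The macrophage list had 7 of 14 and a median of 0.882 ± 0.251 TPM. Its highest members were Ctss (368 ± 29.03 TPM), Cd74 (76.4 ± 40.2 TPM) and Cd68 (11.7 ± 1.05 TPM), and C1qc (0.0766 ± 0.0739 TPM) and Cd14 (0.00907 ± 0.0181 TPM) its lowest. The dendritic cell list had 3 of 12 and a median of 0.112 ± 0.0108 TPM. The detected members were the MHC class II genes H2-Eb1 (19.2 ± 10.8 TPM), H2-Ab1 (16.1 ± 8.46 TPM) and H2-Aa (13.99 ± 6.64 TPM), while the dendritic markers Clec9a (0.0297 ± 0.0593 TPM) and Xcr1 (0.00841 ± 0.0168 TPM) lay near the floor. The thymocyte list had 4 of 8 and a median of 13.4 ± 1.59 TPM, midway between 2 middle members that lie far apart, with Cd1d1 (60.4 ± 4.82 TPM) and Themis (48.6 ± 4.29 TPM) and Cd8b1 above Rag1 (0.00567 ± 0.0113 TPM) and Rag2, which had no count. Granulocyte and mast cell genes had 1 of 12 detected and a median of 0 TPM, with S100a9 (1.46 ± 0.507 TPM), Csf3r (0.424 ± 0.189 TPM) and S100a8 (0.417 ± 0.327 TPM) highest and no count for Fcer1a and Ms4a2. Red cell and platelet genes had 1 of 10 and a median of 0.0629 ± 0.0523 TPM, with Itga2b (3.17 ± 0.559 TPM), Hbb-bs (1.37 ± 1.17 TPM) and Hba-a1 (0.243 ± 0.179 TPM) highest and no count for Pf4 and Ppbp. Stromal genes had 2 of 10 and a median of 0.0116 ± 0.0102 TPM. Pecam1, which T cells also carry, stood at 155 ± 14.7 TPM, above Epcam (2.39 ± 0.556 TPM) and Cdh5 (0.399 ± 0.2803 TPM), and Krt8 and Pdgfra had no count.

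Metabolic and general lists differed widely in level. Ribosomal proteins had all 20 members detected at a median of 1861 ± 56.6 TPM, with Rpl10a (771 ± 42.7 TPM) and Rpl5 (476 ± 37.4 TPM) lowest. Nuclear-coded respiratory chain subunits had all 20 detected at 179 ± 8.01 TPM, from Atp5a1 (677 ± 24.8 TPM), Atp5b (562 ± 13.5 TPM) and Cox4i1 (446 ± 13.6 TPM) to Cox6c (47.2 ± 2.49 TPM) and Ndufs1 (35.4 ± 3.46 TPM). Glycolysis had 15 of 16 detected at 59.5 ± 2.23 TPM, from Ldha (576 ± 15.2 TPM), Pkm (445 ± 18.4 TPM) and Aldoa (398 ± 26.6 TPM) to Slc16a3 (1.72 ± 0.335 TPM) and Hk2 (0.802 ± 0.295 TPM). Cholesterol synthesis had all 16 detected at 24.5 ± 1.34 TPM, from Srebf2 (291 ± 16.5 TPM) and Hmgcs1 (48.4 ± 2.45 TPM) to Fdps (6.99 ± 0.622 TPM) and Idi1 (2.498 ± 0.213 TPM). The type I interferon list had 19 of 20 detected at 43.02 ± 10.1 TPM and percentile 97.4 (76.1 among expressed genes), from Ifi47 (316 ± 23.9 TPM), Igtp (254 ± 22.5 TPM) and Bst2 (201 ± 32.99 TPM) to Mx1 (2.73 ± 1.48 TPM) and Ifi44 (1.32 ± 0.822 TPM). Housekeeping genes had all 12 detected at 263 ± 9.99 TPM, from Eef1a1, Actb and B2m to Tbp (8.302 ± 0.135 TPM). Mitochondrially coded messages had 8 of 13 detected, led by mt-Co1, mt-Cytb and mt-Nd1 (3253 ± 202 TPM). The low values of mt-Co2 (0.142 ± 0.1905 TPM) and mt-Nd4l, which had no count, are uncertain, because all of their sampled 50-base words also occur in other annotated genes. The median of that list was 8.72 ± 1.4998 TPM, and mitochondrial genes took 1.21% ± 0.0914 of counts. Other members share sequence as well, mt-Co1 51.3% of its words, so this median and this share of counts may be too low. Rpl5, Fdps and Idi1 share 60.3%, 51.9% and 42.2% of their words, so their low places are uncertain too. RNAs without a poly(A) tail were low. Replication-dependent histone genes had 9 of 16 detected at a median of 2.15 ± 0.494 TPM, from Hist1h1c (17.7 ± 0.624 TPM), Hist1h4d (14.5 ± 2.67 TPM) and Hist1h1e (9.098 ± 2.06 TPM) to Hist1h3b and Hist2h3c1 with no count. Short RNAs without a tail had 5 of 11 detected at 1.79 ± 0.734 TPM, with Rn7sk (59.9 ± 43.02 TPM), Rnu11 (7.52 ± 1.98 TPM) and Rpph1 (7.36 ± 3.36 TPM) highest, Rny3 (0.137 ± 0.274 TPM) low and no count for Rn7s1. Several histone genes and short RNAs are near-identical copies, whose fragments the counting left out.

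The V segments of the T cell receptor were used broadly. All 22 annotated beta chain V segments had counts in every library, on 11096 to 31008 counts per library. The effective number of beta segments, the exponential of the Shannon entropy of their shares, was 16.1 ± 0.156 (SD, n = 4). The largest share was that of Trbv13-2 at 11.7% ± 0.441 of beta chain counts, on chromosome 6, 41121396 to 41121832. It was followed by Trbv1 at 9.62% ± 0.667, Trbv31 at 9.08% ± 0.748, Trbv16 at 8.78% ± 0.364 and Trbv3 at 8.65% ± 0.178. Of 108 alpha chain V segments, 66 had a count in all libraries, and the effective number was 46.3 ± 1.15 (SD, n = 4). The largest alpha shares were Trav14d-3-dv8 at 7.65% ± 0.795, Trav14n-3 at 5.21% ± 0.197, Trav14-2 at 4.24% ± 0.768, Trav14-1 at 4.22% ± 0.334 and Trav13-1 at 4.11% ± 0.564. These alpha segments share 36.6% to 50% of their sampled 50-base words with other genes, except Trav14-1 at 2.86%, so the division among the others is uncertain.

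The libraries were next compared with each other, without naming a condition, since the labels give none. B cell and MHC class II genes and interferon genes were among those that varied more than genes of like abundance. In edgeR's intercept-only quasi-likelihood fit, 142 of 12554 genes passed an adjusted p of 0.05 for residual deviance, and 657 had an unadjusted p under 0.05. Of the 142, 53 were highest in replicate 1, 41 in replicate 3, 27 in replicate 2 and 21 in replicate 4, and 58 were lowest in replicate 4. By biotype, 102 were protein-coding and 23 of the 385 tested processed pseudogenes were called (5.97%, against 0.945% of protein-coding genes). The count fell to 64 without replicate 1, 85 without replicate 2, 84 without replicate 3 and 60 without replicate 4. A limma fit of log2(TPM+1) called 2 genes, and a fit with no count filter 88. In data simulated for this comparison at the trended dispersion itself, 33.9% of 1.5-fold, 74.6% of 2-fold and 91.0% of 4-fold changes were recovered.

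Of the B cell list, 7 of 9 tested members were called, and 8 when adjusted over the list alone. Igkc, the kappa light chain constant gene, lay at 64.7, 38.2, 34.9 and 11.2 TPM in replicates 1 to 4 (edgeR adjusted p = 9.01e-10, chromosome 6, 70726435 to 70726966). Chosen after their values were seen, the B cell gene Cd79a lay at 13.5, 9.203, 7.61 and 4.098 TPM, and Ighm, which was not called, at 1162, 1156, 1071 and 1023 TPM. The MHC class II genes ran in parallel. Cd74, the invariant chain, lay at 131, 66.6, 73.3 and 34.5 TPM (edgeR adjusted p = 1.47e-27), and H2-Eb1, H2-Ab1 and H2-Aa spanned 1.75, 1.74 and 1.46 on the log2(CPM+1) scale between the highest and the lowest library. Of the macrophage list Cd74 alone was called among 7 tested members, and of the dendritic list these 3 class II genes among 4. Both counts were the same adjusted over the list alone. Of the interferon list, 11 of 20 members were called, and 14 when adjusted over the list alone. Ifit3 lay at 44.2, 24.8, 41.8 and 16.2 TPM in replicates 1 to 4 (edgeR adjusted p = 2.87e-11). Ifit3 shares 51.2% of its sampled 50-base words, most with Ifit3b. The interferon-induced GTPase gene Iigp1, outside the lists, lay at 14.9, 17.02, 7.22 and 6.79 counts scaled to library size (CPM). It was higher in replicates 1 and 2 than in replicates 3 and 4, and so did not follow Ifit3.

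**Figure D3:**
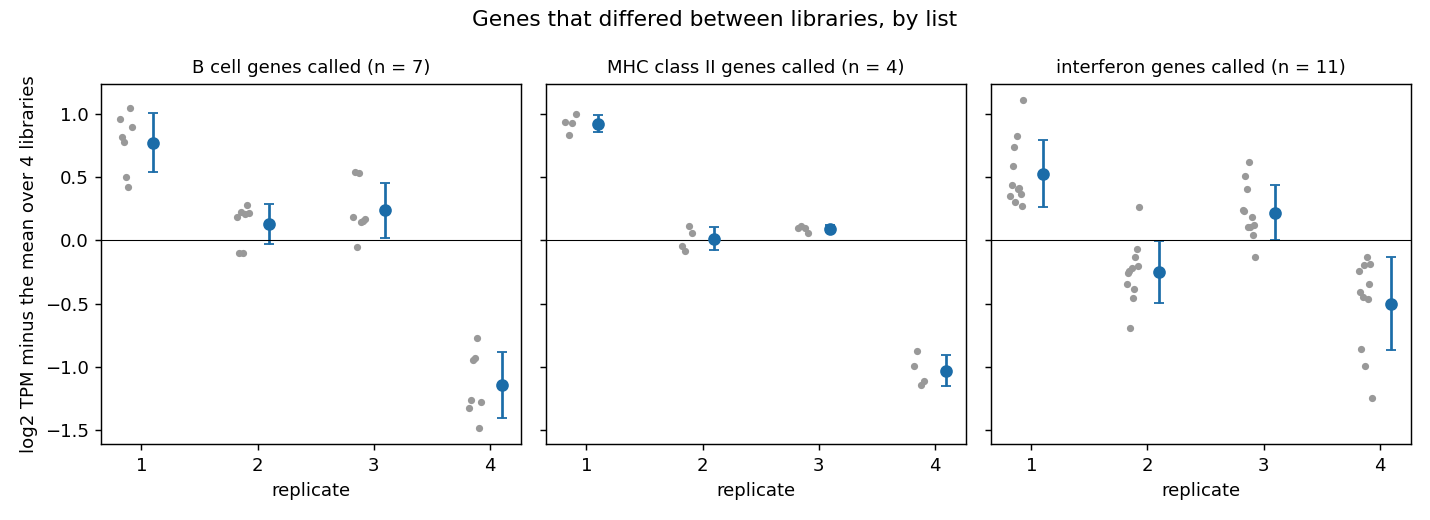
Log2 TPM of called genes of the B cell list, of the MHC class II genes and of the interferon list, each gene as its deviation from its own mean over the 4 libraries (grey points), with the mean and SD over genes in blue. The B cell genes lie at a mean of 0.77 in replicate 1 and -1.14 in replicate 4, and the interferon genes at 0.53, -0.25, 0.22 and -0.50 in replicates 1 to 4.

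Other called genes with a wide range are given one by one. Xist, the RNA that coats the inactive X chromosome, lay at 141, 148, 0.4598 and 0.271 TPM. The heat shock gene Hspa1b lay at 45.04, 37.03, 5.08 and 45.6 TPM, lowest in replicate 3, and shares 62.7% of its sampled words, most with Hspa1a. These were the 2 called of 13 tested members of the immediate early and heat shock list (4 adjusted over the list alone). H2-Q6, on chromosome 17, 35424850 to 35430055, lay at 289, 267, 58.1 and 88.5 CPM (edgeR adjusted p = 3.27e-67), and H2-Q5 at 95.96, 87.7, 31.9 and 44.3 CPM. Both share over 30% of their words, most with H2-Q7. Rnf157, on chromosome 11, 116336353 to 116413032, lay at 2.44, 8.502, 9.29 and 14.1 CPM. The short RNA Rn7sk lay at 5.19, 2.61, 3.28 and 11.8 CPM, highest in replicate 4. Cfap74 and the overlapping transcript 5830444B04Rik lay at 13.1, 13.5, 8.73 and 3.93 and at 6.45, 8.31, 6.87 and 2.64 CPM, lowest in replicate 4. Arhgap18 lay at 16.5, 15.3, 4.93 and 14.3 CPM and Coro2a at 24.8, 18.2, 9.98 and 14.99 CPM, both lowest in replicate 3. Il2ra, the only regulatory T cell gene called among 15 tested (2 adjusted over the list alone), lay at 6.22, 3.63, 9.13 and 3.11 TPM (edgeR adjusted p = 1.19e-07). The ribosomal protein pseudogenes Rps18-ps3 and Rps15a-ps6 lay at 3.42, 5.89, 11.8 and 9.49 and at 3.03, 5.25, 8.25 and 7.39 CPM. They share 80.5% and 54.3% of their words with other genes, so their counts are uncertain. None of the 15 naive and central memory genes and none of the 18 T cell receptor complex genes was called, also adjusted over each list alone. Of the 5 RNAs that tell female from male cells, the Y-linked Ddx3y lay at 0.238, 0.0988, 75.2 and 76.1 TPM, Eif2s3y at 0.265, 0.1097, 52.4 and 63.2, Kdm5d at 0.0726, 0.0263, 21.4 and 20.9 and Uty at 0, 0.03497, 9.78 and 10.1 TPM in replicates 1 to 4. With Xist, these values give replicates 1 and 2 the pattern of female cells and replicates 3 and 4 that of male cells. The single donor record therefore cannot stand for 1 animal. The labels give no sex for these samples. For genes that separate the same pairs, such as H2-Q6, H2-Q5 and Iigp1, sex cannot be told apart from other differences between the pairs.

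Whole lists were also followed across libraries, as the mean log2(CPM+1) over members. The B cell list deviated from its 4-library mean by 0.44, 0.03, 0.10 and -0.57 in replicates 1 to 4, an SD of 0.42 against a median of 0.05 for random lists of matched expression. The interferon list deviated by 0.31, -0.13, 0.12 and -0.29, with an SD of 0.26. In all, the SD of 20 of 42 lists exceeded that of 95% of 10000 random lists, against 4 of 39 unmoved lists in simulated data. The 20 fell to 9 in log2 TPM, 8 with the median over members and 11 among genes of at least 5 CPM. Members of a list can be regulated together, so chance among independent genes is only a reference. Besides the sex list, the B cell and interferon lists alone stayed past that level under all 9 alternatives tried. The heat shock list deviated by 0.06, -0.01, -0.26 and 0.21, the dendritic list by 0.20, 0.02, 0.01 and -0.23, the activation list by -0.03, -0.09, 0.21 and -0.09 and the ribosomal protein list by -0.06, -0.09, 0.07 and 0.08. Each of these 4 passed under 8 of 9 alternatives. The activation list lay at percentile 69.2 without replicate 3. The heat shock, dendritic and ribosomal protein lists lay at percentiles 58.8, 6.0 and 91.4 when the median over members replaced the mean. The regulatory T cell list lay at percentile 97.9 and at 41.1 with the median over members. The naive and central memory list and the T cell receptor complex list lay at percentiles 77.3 and 33.2.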

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

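Of 244 values reported per library (list means, ratios, library measures and named genes with a mean of at least 10 counts), 14 had a library whose gap to its nearest neighbour took an unusually large part of the range of the 4. Chance gives about 1 in 20, or 12.2 of 244, so the number of such values is close to chance. The outlying library was replicate 2 in 5, replicate 3 in 4, replicate 1 in 3 and replicate 4 in 2 of them.

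Among lists, the lineage factor list stood apart in replicate 3 (gap ratio 0.837), at a mean log2(CPM+1) of 3.27 against 3.05 to 3.09 in the others. The mitochondrial message list stood apart in replicate 1 (ratio 0.8292), at 5.26 against 5.38 to 5.41. Among genes of stress and cell death, Bax was lowest in replicate 2 at 138 TPM against 157 to 159 (0.884), and Trp53inp1 lowest in replicate 4 at 118 TPM against 135 to 137 (0.874). Smad7, an inhibitor of transforming growth factor beta signals, was lowest in replicate 2 at 134 TPM against 148 to 149 (0.917). Epas1 was highest in replicate 4 at 27.8 TPM against 25.2 to 25.4 (0.946). Among T cell genes, Il6ra was highest in replicate 2 at 254 TPM against 233 to 234 (0.960). Cd40lg was lowest in replicate 3 at 259 TPM against 271 to 273 (0.8396). Tigit was lowest in replicate 1 at 0.858 TPM, on 6 counts, against 1.56 to 1.68 (0.848). Trac was lowest in replicate 1 at 3229.9 TPM against 3483 to 3516 (0.885). Among metabolic genes, Hmgcs1 and Ndufs1 were highest in replicate 2, at 52.0 TPM against 46.9 to 47.3 (0.922) and at 40.6 TPM against 33.4 to 34.4 (0.857). The haemoglobin gene Hbb-bs was highest in replicate 3 at 3.12 TPM against 0.727 to 0.896 (0.929), and the histone gene Hist1h1e lowest in replicate 3 at 6.01 TPM against 9.94 to 10.2 (0.933).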

How the results depend on the processing

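The added alternatives, chosen after seeing the data, were the filter on 10 counts in 2 libraries, thinned libraries and the list spread over genes with at least 5 CPM. The alternatives with posterior mean TPM were not run, since the files hold raw counts. No paired analysis was possible because there is 1 group. All 24 alternatives for the Foxp3 ratios kept their sign, and so did 105 of 112 for the regulatory T cell list against other lists. With the mean over members the difference turned to -0.38 against the CD8 list and -0.11 against the B cell list, and without Foxp3, Il2ra and Ctla4 to -1.22, -0.62 and, against thymocytes, -0.17. Without 1 library the CD8 difference ran from -0.12 to 0.27. The percentile of the regulatory T cell list was 0 among random lists of expressed genes. There 22 of the 42 list percentiles moved by more than 5 points or across the middle of the random lists. The naive list's median was 638 TPM over nuclear protein-coding genes, a smaller denominator. That setting moved 23 of 42 list medians by more than their SD between libraries, 18 up and 5 down, and smaller rises were not counted. The falls were from 722 to 515 TPM in the T cell receptor complex, 3.42 to 1.21 in the B cell list, 0.603 to 0.0136 in the gamma-delta list, and to 0 in the mitochondrial messages and short RNAs, whose genes it leaves out in part or whole. At 5 TPM in place of 1 TPM, 15 of 42 counts of detected members fell by more than 1.5-fold. They fell from 11 to 5 for effector regulatory T cells, 15 to 7 for dividing cells, 7 to 3 for each of T helper 1, B cell and macrophage genes and 3 to 0 for T helper 17. Smaller falls are left out of the 15, such as 13 to 9 for the regulatory T cell list. At 0.5 TPM 1 count rose by more than 1.5-fold. Smaller rises included 13 to 14 for the regulatory T cell list and 7 to 9 for T helper 1. The count of variable genes was 88 with no filter (71 shared with the 142), 2 with limma, 60 to 85 without 1 library, 139 with DESeq2 size factors, 115 with DESeq2's trend, 104 with 10 counts in 2 libraries and 115 in thinned libraries. The added filter brought in the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty. Lists past the 95th percentile of spread numbered 9 in log2 TPM, 8 with the median over members, 11 among genes of at least 5 CPM and 14 to 20 without 1 library. The biological coefficient of variation ran from 0.0772 to 0.0903. Over detected genes alone, the lowest Pearson and Spearman correlations were 0.9885 and 0.9897. Except where given, the cause was not tested. Leaving out a library also removes 1 of 3 residual degrees of freedom. Detected genes ran from 9504 to 12558, and the effective numbers of V segments from 16.1 to 16.2 and from 46.0 to 47.0. In the shallower libraries genes below about 1 TPM rest on few counts, and with 4 libraries no sign-flip test can pass 0.05.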

Other observations

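All explanations below were tested after the results were seen, and the genes named here outside the fixed rule were chosen after their values were seen. The design has 1 group, so no biological explanation for a difference between libraries was tested. The explanations weighed are technical, RNA from cells of another type among them.

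Some genes changed between libraries in ways that no list describes. The peptide transporter gene Slc15a2 (chromosome 16, 36750178 to 36784962) lay at 25.6, 5.52, 0.0864 and 10.8 CPM in replicates 1 to 4, on 650, 345, 2 and 660 counts. The phosphodiesterase gene Pde3b lay at 306, 386, 208 and 186 CPM and the chaperone gene Hsph1 at 177, 121, 125 and 236 CPM. H2-Q7, next to H2-Q6 on chromosome 17, lay at 965, 880.2, 439.6 and 536 CPM. The X-linked genes Kdm6a, Kdm5c and Eif2s3x, which have Y-linked partners, lay at 123, 132, 75.02 and 82.2, at 343, 317, 224 and 248 and at 43.8, 46.4, 31.98 and 34.7 CPM. The 24 called processed pseudogenes, including 1 transcribed, had a median of 8.08, 9.58, 13.2 and 12.5 CPM in replicates 1 to 4. Replicates 1 and 2 were also the lower pair for the Y-linked genes and the higher pair for Xist. Sex therefore cannot be told apart from other differences between these pairs. The receptor genes Cd4 and Cd8a lay at 1067 ± 31.4 and 0.794 ± 0.288 TPM, while Cd8b1 lay at 39.95 ± 2.55 TPM (SD, n = 4).

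The first pattern is the low level of regulatory T cell genes beside high naive T cell genes in libraries labelled regulatory T cell. Loss of fragments to shared sequence is argued against by the sharing of 50-base words, whose median over the 19 measured regulatory T cell genes was 0% and whose highest value was 16.8%. Counting on the wrong strand is argued against by the T cell receptor complex, whose median was at least 718 TPM in every library. A hypothesis that stays open is that the libraries may hold mostly naive T cells: 14 suppressor genes outside the regulatory T cell list had a median of at most 0.449 TPM in any library, and the log2 ratio of Il7r to Il2ra was 7.41 ± 0.81 (SD, n = 4). The suppressor value does not tell naive conventional cells from resting regulatory T cells. The high ratio of Il7r to Il2ra, and Foxp3 at 8.28 TPM, argue against mostly regulatory T cells, resting ones included. So does the regulatory T cell list, at a median of 5.17 TPM against 569.7 TPM for the naive list. Izumo1r and Tnfrsf18 of that list stood higher, at 167 and 107 TPM. No reference library of regulatory T cells was analysed here, so this is not settled. The file headers carry the text mmTreg and the text activated before the 0 h mark. Whether this bears on the hypothesis was not tested.

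The second pattern is the difference in B cell genes between libraries. Depth as the whole cause is argued against by replicates 2 and 4, whose totals of 62090744 and 61943411 are nearly equal. Between them the 8 B cell genes with at least 1 CPM, leaving out Ighm, differed by a median of 1.04 ± 0.16 (log2, replicate 2 higher, bootstrap error). Between replicates 1 and 3, the other pair of close totals, they differed by 0.69 ± 0.18. Bootstrap errors here and below are over genes, which can move together, so they do not measure the spread between libraries. B cells in varied amounts remain a candidate source. Cd74, H2-Aa, H2-Ab1 and H2-Eb1 are genes that B cells carry and 2 other lists hold. They were higher in replicate 1 than in replicate 4 by a median of 1.94 ± 0.10 on the same scale. These genes had already been called variable, so that value restates the pattern and is no separate support for a source. Macrophages or dendritic cells as a source cannot be told apart from B cells here. Their genes outside MHC class II with at least 1 CPM, Cd68, Itgam, Fcgr3, Ctss and Cebpb, had a median difference of -0.11 ± 0.21, but Ctss at 137 to 157 CPM would hide a small share, the other 4 lay under 5 CPM and the markers of dendritic cells lay near the floor. The most abundant of the 8 B cell genes, Igkc, reached 64.7 TPM, and the high level of Ighm, 1103 TPM, would hide a change of that size; whether a sort removed B cells is not given in the sources used here.

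The third pattern is the difference in interferon genes between libraries. Depth does not account for the differences within pairs of close totals. Replicates 2 and 4 differed by a median of 0.19 ± 0.08 (log2, bootstrap error over genes) and replicates 1 and 3 by 0.18 ± 0.04. The genes lay higher in the libraries with the smaller totals, replicates 1 and 3, by a median of 0.45. The pairs do not bear on depth as a cause of that larger difference. With libraries thinned to equal depth, the spread of the interferon list over the 4 libraries stayed past the 95th percentile of random lists. Its lowest percentile under any alternative was 99.68. That argues against depth as the source of the list's spread, though the 0.45 was not recomputed in thinned libraries. B cells as carriers of these transcripts cannot be told apart from another source: between replicates 3 and 2, interferon genes differed by a median of 0.34 ± 0.23 (log2, bootstrap error) more than B cell genes, which is under 2 errors. Library batches that go with the totals also cannot be told apart from differences between the animals, and no label gives a batch. Of the 20 genes, 13 lay higher in both libraries with the smaller totals than in both with the larger. Chance gives 3.33 on average, but genes that move together can share 1 chance order of the 4 libraries. The 13 is therefore not counted as evidence of a batch.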
